A study of Drosophila melanogaster with 3 samples.

How the data were processed

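Third-instar larval wing discs of Drosophila melanogaster were profiled by CUT&Tag, in which a transposase is tethered to an antibody so that DNA near the bound protein is tagged and sequenced. The larvae expressed an HA-tagged BunA isoform of bunched from a UAS transgene under the nubbin driver, together with GFP, and the antibody recognised the HA tag. Per the labels, flies were kept at 25 °C, the dissected discs were dissociated at 37 °C, and libraries were made with a commercial Vazyme kit. All 3 libraries belong to 1 group, named here BunA-HA wing disc, and are numbered in accession order as replicates 1 to 3, which correspond to the numbers 2, 3 and 4 in their titles. The labels do not say whether the libraries came from separate crosses or larvae, so the SD between them may be technical. No library without the tagged protein or with another antibody was analysed here.

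The deposited files are 3 peak lists, 1 per library, on the dm6 assembly. Per the submitters' processing notes the tools were FastQC, Trim Galore, Bowtie2, Bowtie, MACS2, R 4.2.1, ChIPseeker, HOMER and deepTools. Which of the 2 Bowtie aligners mapped the reads, the versions of the aligner and of MACS2, the fragment filter and the treatment of duplicate or multiply mapping reads are not given in the sources used here. Peak names in the deposited lists carry the name of a single library, so peaks were called per library. For each peak the authors' lists give a start, an end and a summit offset in bp, a fold enrichment at the summit as a linear ratio over the background estimated by the caller, a −log10 p-value and a −log10 q-value. The score column of the deposited lists equals 10 times the −log10 q-value cut to a whole number in 99.99% of the peaks (mean of the libraries). The lowest −log10 q-value was 2.02 ± 0.0116 (SD, n = 3), so the deposited lists hold peaks with a q-value below 0.01. The peak lists hold no read counts, so the sequencing depth of each library is unknown, and no interval for counting error is given. Fold enrichment and the −log10 p-value are the authors' values for single peaks. They were used only to describe peaks and to rank them within a library.

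Peaks on the chromosomes 2L, 2R, 3L, 3R, 4, X and Y were merged where they overlapped by at least 1 bp, and a merged region with a peak of each library is called a consensus region. The centre of a region is the mean of its summits, and its fold enrichment is the mean over libraries of the highest peak value in each. Its percentile is the mean over libraries of the within-library percentile of that value. Genes came from the NCBI RefSeq gene table of the same assembly, Release 6 plus ISO1 MT, which gives the start and end of 17807 genes on these chromosomes, 13946 of them protein coding. The table used here has no strand, exons or transcription start sites. Windows of 1000 bp around transcription start sites, planned before the data were examined, were therefore replaced by windows of 1000 bp on either side of both gene boundaries. The planned promoter, exon, intron and intergenic classes became near a gene boundary, inside a gene and outside genes, taken at the region's centre. A gene counts as bound at a boundary when a consensus region overlaps a window, and as bound in or near the gene when a region overlaps the gene or its 1000 bp flanks. Unless stated otherwise, the fold given for a gene bound at a boundary is that of its strongest boundary region. Some of these genes had a stronger region inside. No genome sequence was used here, so the planned tests of 26 motifs, the Scalloped motif included, were not run, and whether a region is exonic or intronic is not stated.

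The share of each library's peaks overlapped by peaks of both others was compared with 100 random placements within chromosomes, and the position classes with 1000 placements (one-sided permutation tests). Gene lists were written before the data were examined: 21 by hand and 13 by symbol patterns. The hand-written lists cover the Hippo pathway, Yorkie and Scalloped targets, wing disc patterning, the Notch, EGFR, Wingless, Dpp and Hedgehog pathways, JNK, JAK-STAT and apoptosis, insulin and TOR growth control, the cell cycle, the ecdysone response, Hox genes, Polycomb and trithorax, cell adhesion and polarity, sequences carried by the transgenes, and markers of myoblasts, tracheal cells, haemocytes, neurons and fat body. The symbol patterns took cytoplasmic and mitochondrial ribosomal proteins, the proteasome, the vacuolar ATPase, chemosensory receptors, odorant-binding proteins, cuticular proteins, gut serine proteases, cytochrome P450 genes, histones, Osiris genes, chorion and vitelline membrane genes, and tRNA genes. Of 459 names written by hand, 8 matched no gene or more than 1, among them Dl, Tor and d, and were left out. The symbol patterns also took in the cyclophilin Cyp1 and the centriolar gene Cp110, and larp entered the fat body list through a synonym. For 33 lists the number of bound protein-coding members was tested with an exact stratified hypergeometric test within deciles of gene length, two-sided, with Benjamini-Hochberg adjustment over the lists; tRNA genes are given as a share. The strength of the bound members' highest region was compared with 100000 random draws of bound protein-coding genes (two-sided permutation test on the median percentile, lists with at least 3 bound members). Genes on X and on the large autosome arms were compared with Fisher's exact test, two-sided.

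Genes named in the text follow a rule fixed beforehand: the genes nearest to the 15 regions with the highest mean percentile, up to 4 bound members with the highest percentile and up to 2 members without a boundary region per list, and any member of the Hippo pathway, Yorkie and Scalloped target and transgene lists. Any other gene is said to have been chosen after its values were seen. Glg1 and Ptp61F, named as genes around some of the strongest regions, also fall outside the rule. On simulated data with 13946 genes, the gene list test recovered 100% of 10 planted lists and gave p below 0.05 for 3.67% of 300 random lists. Without length strata that share was also 3.67%. The simulated regions were placed at random. The real rise of the bound share from 12.9% in the shortest length decile to 41.8% in the longest was therefore not reproduced. The simulation does not test the allowance for length or regions shared by clustered genes. On simulated data with 3000 genes, the median test recovered 100% of 60 planted lists and gave p below 0.05 for 3.33% of 60 random ones. The alternatives were leaving out each library, regions in at least 2 libraries, 50% reciprocal overlap, and windows of 500 and 2000 bp. Others were the gene list test without strata, peak numbers on the main chromosomes alone, and region strength ranked by −log10 p-value. A further alternative kept only peaks above the median fold enrichment of their library. These are called the higher scoring peaks, and the rest the lower scoring ones. Added after the data were seen were regions anywhere in the gene, strata by number of RefSeq transcripts, strata by length and a neighbouring gene, and length strata for X-linked genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.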

Results

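The 3 CUT&Tag libraries were made with an antibody against HA from wing discs, the larval precursors of the adult wing, that expressed HA-tagged BunA under the nubbin driver, which is active in the wing pouch. bunched (bun) is the Drosophila member of the TSC22 family, and the series title places it in growth control by the Hippo pathway. The libraries held 9268, 9005 and 9225 peaks, 9166 ± 141 (SD, n = 3). Median peak width was 157, 163 and 160 bp, and the peaks covered 1.62 ± 0.0203 Mb per library. Median fold enrichment over the caller's background, the authors' value for each peak, was 6.61, 7.15 and 6.98. The design has 1 group and no comparison between groups, so the questions asked here are which positions recurred between libraries and which genes lay beside them. A gene is called bound where such a region lies, a term for the peaks alone, since no control library was analysed here to set antibody signal apart from open chromatin.

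Anti-HA peaks recurred at the same positions in the 3 libraries, and the recurring positions included the boundaries of wg, which encodes the Wingless ligand, rho, which encodes a protease that releases EGFR ligands, and Akt, a kinase of insulin signalling. Merging gave 10871 regions on the main chromosomes. Of these, 5768 (53.1%) had a peak in all 3 libraries, 1869 (17.2%) in 2 and 3234 (29.7%) in 1. Regions of all 3 libraries had a median fold enrichment of 8.2, against 5.61 for regions of 2 libraries and 4.99 for regions of 1. These 5768 consensus regions had a median width of 237 bp and covered 1.58 Mb, 1.15% of the chromosomes. Of each library's peaks, 71.2% ± 0.722 (SD, n = 3) were overlapped by peaks of both other libraries, against a mean of 0.0600% and a maximum of 0.105% in random placements (one-sided permutation test, p = 0.0099, the smallest that 100 placements can give). Sharing was 91.6% ± 0.985 for the higher scoring peaks of each library, those above its median fold, and 49.9% ± 1.75 for the others. Spearman correlations of fold enrichment across shared peaks, which are not independent replicates, were 0.794, 0.807 and 0.820 for the 3 pairs of libraries.

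Consensus regions gathered at the boundaries of annotated genes and were sparser inside and between genes. Centres of 2790 regions (48.4%) lay within 1000 bp of a gene boundary, against 28.3% ± 0.598 (SD of placements) at random, a ratio of 1.71 (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). A further 2166 regions (37.6%) lay inside a gene and farther from its boundaries, where random placement gave 48.5%, and 812 (14.1%) lay over 1000 bp outside any gene, where it gave 23.2%. The peaks of single libraries had shares of 46.4% ± 1.43, 37.4% ± 0.640 and 16.2% ± 0.801 (SD, n = 3) in these classes. A gene boundary here is either end of the gene, since strand was not used. Random positions were drawn evenly over each whole chromosome. Sequence where peaks can hardly be called was not set apart, and its part in the difference was not measured.

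**Figure D1:**
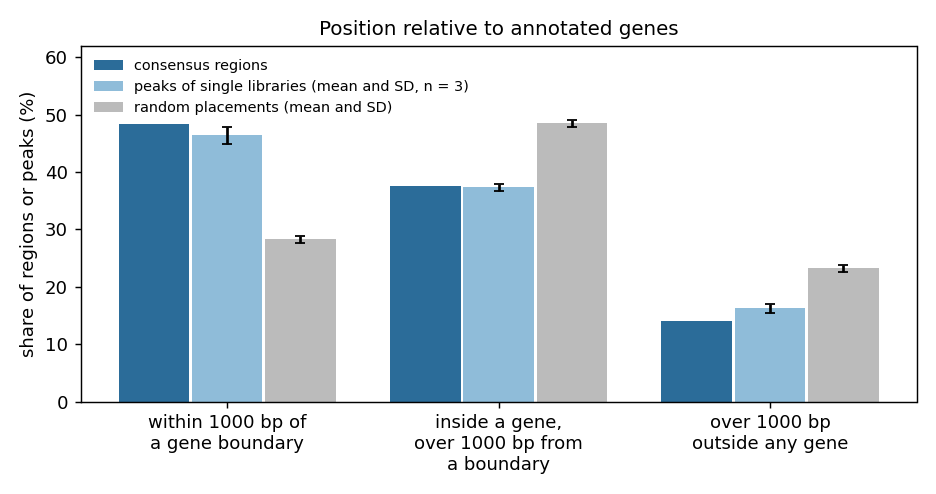
Share of consensus regions, of the peaks of single libraries (mean and SD of 3 libraries) and of random placements (mean and SD) in 3 position classes relative to annotated genes, in percent. The class within 1000 bp of a gene boundary holds 48.4% of consensus regions against 28.3% at random, and the other classes hold fewer regions than random placement.

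The highest fold enrichments stood in sequence near the centromere of chromosome 2R, on the Y chromosome and beside a few developmental genes. The region with the highest fold, at 870230 to 870563 on 2R, reached 74.7 ± 0.599 (SD, n = 3) and lay 14725 bp from the nearest gene, CG46302. Another on 2R, at 748754 to 748932, reached 52.0 ± 2.87 and lay 43005 bp from DIP-lambda. Among the 15 regions with the highest percentile, 6 were on Y: near ORY (58.4 ± 1.68), inside kl-5 (50.2 ± 1.09 and 35.8 ± 0.758) and kl-2 (38.7 ± 0.641), which encode axonemal dyneins of sperm, inside Ppr-Y (34.0 ± 0.875) and 11621 bp from PRY (36.7 ± 2.28). Others lay inside Pzl on 3R (33.6 ± 2.81) and 225 bp from the boundary of the antisense gene asRNA:CR43933 in Glg1 on 3L, where the libraries differed more (38.8 ± 10.6). The region beside wg, at 7306868 to 7307160 on 2L and centred 190 bp outside the gene, had a fold of 30.6 ± 1.07. That in Akt, at 16099746 to 16099988 on 3R, had 29.6 ± 2.16, and that beside rho, at 1463553 to 1463864 on 3L, 79 bp outside the gene and within Ptp61F, had 26.8 ± 1.09. A region in homer, a synaptic scaffold gene, on 2L had 27.8 ± 2.84, and a region at mir-954 and the TGF-beta ligand gene mav on chromosome 4 had 26.8 ± 1.78.

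Genes of the Hippo pathway, the growth-restricting kinase cascade named in the series title, carried regions from its cadherins at the cell surface to its nuclear effectors. Boundary regions lay at 18 of 35 listed genes (51.4%), where gene length alone gave 32.9%, and this difference did not pass the threshold (exact stratified test, adjusted p = 0.0667). The atypical cadherin genes ft and ds had regions of fold 13.4 ± 1.71 and 14.3 ± 0.755 (SD, n = 3), and fj, which encodes a Golgi kinase acting on them, had 13.9 ± 2.0. The core kinase genes hpo and wts had 12.9 ± 0.101 and 8.67 ± 2.01 at a boundary, and a stronger region inside wts had 18.6 ± 1.52. At yki, the coactivator gene, a region at 24068944 to 24069098 on 2R, 558 bp outside the gene, had 9.02 ± 1.79, and at sd, which encodes its DNA-binding partner Scalloped, a region 106 bp outside the gene on X had 6.79 ± 0.774. A stronger region inside sd, at 15811692 to 15812518, had 20.3 ± 0.590. Upstream regulators were bound as well: kibra (15.7 ± 2.58), crb (15.7 ± 1.55), Pez (17.3 ± 2.70), Fbxl7 (12.6 ± 1.06), dco (13.1 ± 0.188) and Cka (20.3 ± 3.18), a part of the STRIPAK phosphatase complex. The others with a boundary region were ex, tsh, Tgi, scrib and mnb.

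Another 6 Hippo genes had consensus regions only deeper inside the gene: hth, which encodes a homeodomain partner of Yorkie, with 21 regions, sdt with 5, and dlg1, jub, Tao and l(2)gl with 1 each. No consensus region was found in or near mats, sav, Mer, Rassf, Wbp2, Zyx, app, Patj, aPKC, lft and Mob4. Single libraries did have peaks in or near some of these genes: lft in all 3 libraries, Rassf and Mob4 in 2, and mats and aPKC in 1. Counting regions anywhere in the gene or its flanks, an alternative chosen after the data were seen, 24 of 35 genes (68.6%, 43.7% expected) were bound, with an exact adjusted p of 0.00433. With replicate 1, 2 or 3 left out, which asks for a peak in only the other 2 libraries, the adjusted p for boundary regions was 0.0267, 0.0422 and 0.0403, within a range of 0.000163 to 0.0676 over 11 alternatives. Where Hippo genes were bound at a boundary, their regions ranked high: the median percentile was 89.1, against 72.1 for random bound genes (permutation test, adjusted p = 0.0223). The random genes were not matched for length or for the number of boundary regions, of which the strongest was taken.

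Targets of Yorkie and Scalloped, the genes through which the pathway sets growth and survival, had regions at their boundaries more often than genes of their length. Boundary regions lay at 16 of 22 protein-coding targets (72.7%), where 35.8% were expected (exact stratified test, adjusted p = 0.00167), and the library means were 80.3% ± 6.94 (SD, n = 3). The bound targets ex, fj, Tgi, kibra and crb and the unbound Mer are on the Hippo list too, so the list tests are not independent. Diap1, the caspase inhibitor gene, had 6 regions in or near it, of which the one 104 bp outside the boundary, at 16051050 to 16051221 on 3L, had a fold of 10.3 ± 1.77. At ex, both a target and an upstream regulator, the boundary region at 430908 to 431097 on 2L had 4.77 ± 1.04, and the strongest of 5 regions had 9.40 ± 0.845. Regions of growth and signal genes included vn (13.8 ± 1.90), an EGFR ligand gene, Ser (11.7 ± 2.69), a Notch ligand gene, Krn (10.2 ± 1.17) and CycB (10.7 ± 2.53). A stronger region inside Ser had 18.4 ± 3.49. The neighbours InR, the insulin receptor gene, and E2f1, a cell cycle transcription factor gene, shared a region of 9.61 ± 1.92 between them and held 11 and 13 regions in or near the gene. The wing selector gene vg had 7.41 ± 0.754, the glypican gene dally 5.0 ± 1.17 and upd1 6.55 ± 1.19. A stronger region inside dally had 15.3 ± 0.363. Myc, CycE and dlp had regions inside the gene only, of 11.9 ± 1.88, 13.1 ± 0.606 and 10.9 ± 1.35. Mer, upd2 and upd3 had no consensus region, though upd2 and upd3 each had a peak in or near the gene in 2 libraries. The ranks of the target regions did not pass the threshold (median percentile 77.5 against 72.1, permutation test, adjusted p = 0.676).

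**Figure D2:**
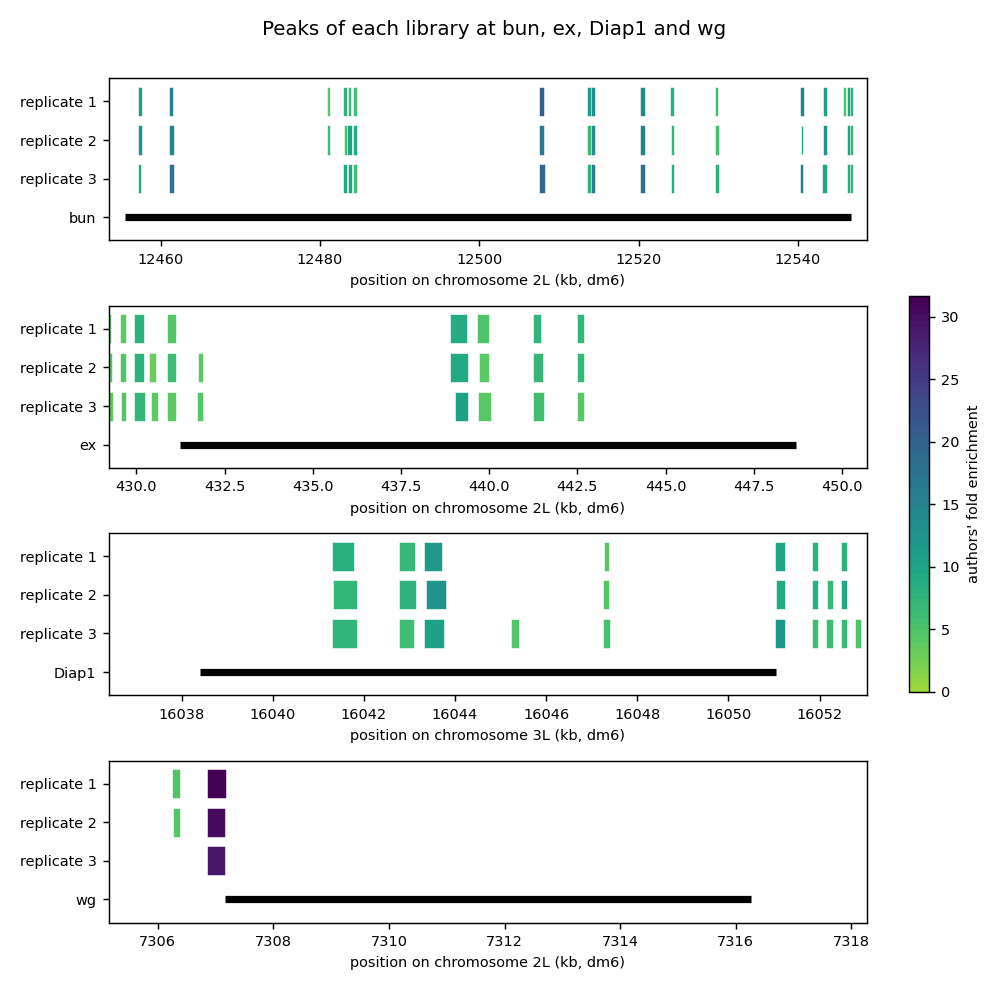
Peaks of replicates 1 to 3 at bun, ex, Diap1 and wg, drawn to scale against dm6 positions in kb with a thin outline, with the gene as a black bar and the colour giving the authors' fold enrichment. The wg peak just outside the gene has a fold of 30.6 ± 1.07 (SD, n = 3), and bun carries 15 consensus regions along its length.

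Genes that pattern the wing disc had the highest bound share of the developmental lists, and several signalling pathways that act in the disc were over-represented with them. The lists share members, so their tests are not independent. The gene wg is on the target, patterning and Wingless lists, and salr is on the patterning and Dpp lists. The target list shares vn with the EGFR list and Ser with the Notch list. Of genes without a boundary region, dpp is on the patterning and Dpp lists. Of 45 patterning genes, 40 (88.9%) had a boundary region, against 37.1% expected (exact stratified test, adjusted p = 2.57e-12), and 44 had a region in or near the gene. Beside wg these were led by Dr (23.2 ± 2.22; SD, n = 3), salr (22.1 ± 2.85) and tup (20.9 ± 1.09), which encode transcription factors. dpp and hth had regions inside the gene only. In the Notch pathway 17 of 26 genes (65.4%, 24.6% expected, exact adjusted p = 2.40e-05) were bound, among them mib1, a ubiquitin ligase gene for Notch ligands (18.4 ± 3.44), and E(spl)mdelta-HLH, a Notch target (13.0 ± 1.49), but not dx or E(spl)m4-BFM. In the EGFR pathway 15 of 22 (68.2%, 37.1% expected, exact adjusted p = 0.0102) were bound, with csw (14.6 ± 1.52), a phosphatase gene, and ed (12.6 ± 1.08) beside rho and vn, while cic was bound only inside and Dsor1 not at all. With the higher scoring peaks alone the EGFR list had an exact adjusted p of 0.117, within a range of 7.68e-06 to 0.117 over 11 alternatives.

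The Dpp and ecdysone lists also passed, each with exceptions under other settings. On the Dpp list 12 of 19 genes (63.2%, 33.5% expected, exact stratified test, adjusted p = 0.0303) were bound, including the receptor gene sax (20.8 ± 3.96; SD, n = 3) and the Smad gene Smox (15.8 ± 2.44), but not babo. Smox and babo act in the Activin branch of TGF-beta signalling, so the list is wider than the Dpp pathway itself. The Dpp call was lost without replicate 3 (11 of 19, exact adjusted p = 0.0951) and with windows of 2000 bp (0.0891), the range over 11 alternatives being 0.000181 to 0.0951. Of the ecdysone response genes, which time larval moults and metamorphosis, 12 of 16 (75%, 38.5% expected, exact adjusted p = 0.0102) had a boundary region, and 16 of 16 had one in or near the gene. They were led by the nuclear receptor gene ftz-f1 (19.4 ± 2.15), Eip74EF (18.9 ± 2.13), Hr39 (14.8 ± 1.75) and Hr3 (11.5 ± 0.616), and Eip63E and Eip93F were bound inside only. With the higher scoring peaks alone the ecdysone list had an exact adjusted p of 0.0576, within a range of 1.62e-05 to 0.0576.

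Other developmental lists had shares above expectation that did not pass the threshold. They were the Wingless pathway (12 of 23, 36.9% expected, exact stratified test, adjusted p = 0.213), with the receptor gene fz (17.4 ± 2.51; SD, n = 3) and arm, the beta-catenin gene (16.6 ± 3.22), and the Hedgehog pathway (8 of 14, 30.9% expected, adjusted p = 0.0854), with cos (19.6 ± 2.01), en (16.4 ± 2.62) and the receptor gene ptc (12.1 ± 1.43). Insulin and TOR growth control had 14 of 24 (35.1% expected, exact adjusted p = 0.0677), with Lnk (14.2 ± 2.26) beside Akt. The JNK, JAK-STAT and apoptosis list had 14 of 30 (29.7% expected, exact adjusted p = 0.0854), with grnd, a tumour necrosis factor receptor gene (17.3 ± 0.503), dome (18.0 ± 3.12) and the cell death gene hid (13.0 ± 1.27). The Hedgehog list passed without replicate 1 (exact adjusted p = 0.0452) or 3 (0.0403), the insulin list without replicate 1 (0.0183), and the JNK list without replicate 2 (0.0111) or 3 (0.0371). Over 11 alternatives the Hedgehog and JNK lists each passed in 6 (exact adjusted p from 0.00548 to 0.151 and from 0.00236 to 0.277), the insulin list in 4 (0.000168 to 0.197) and the Wingless list in 2 (0.00196 to 0.771). Hox genes had 5 of 8 at a boundary and 8 of 8 in or near the gene, led by lab (17.1 ± 3.10) and pb (16.7 ± 2.04), with exact adjusted p of 0.352 and 0.0582. Shares were 11 of 26 for Polycomb and trithorax genes (32.4% expected, exact adjusted p = 0.352), led by Su(z)2 (15.7 ± 1.23). They were 14 of 31 for adhesion and polarity genes (35.9% expected, exact adjusted p = 0.396) and 13 of 39 for cell cycle genes (22.4% expected, adjusted p = 0.194), where dup (12.8 ± 2.27) and the phosphatase gene stg (9.66 ± 1.17) were bound and the kinase genes aurA and aurB were not. The cell cycle list passed with windows of 500 bp (exact adjusted p = 0.0347, range 0.0347 to 0.185), and the Hox, Polycomb and adhesion lists passed only without length strata (0.0192, 0.0192 and 0.00526).

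**Figure D3:**
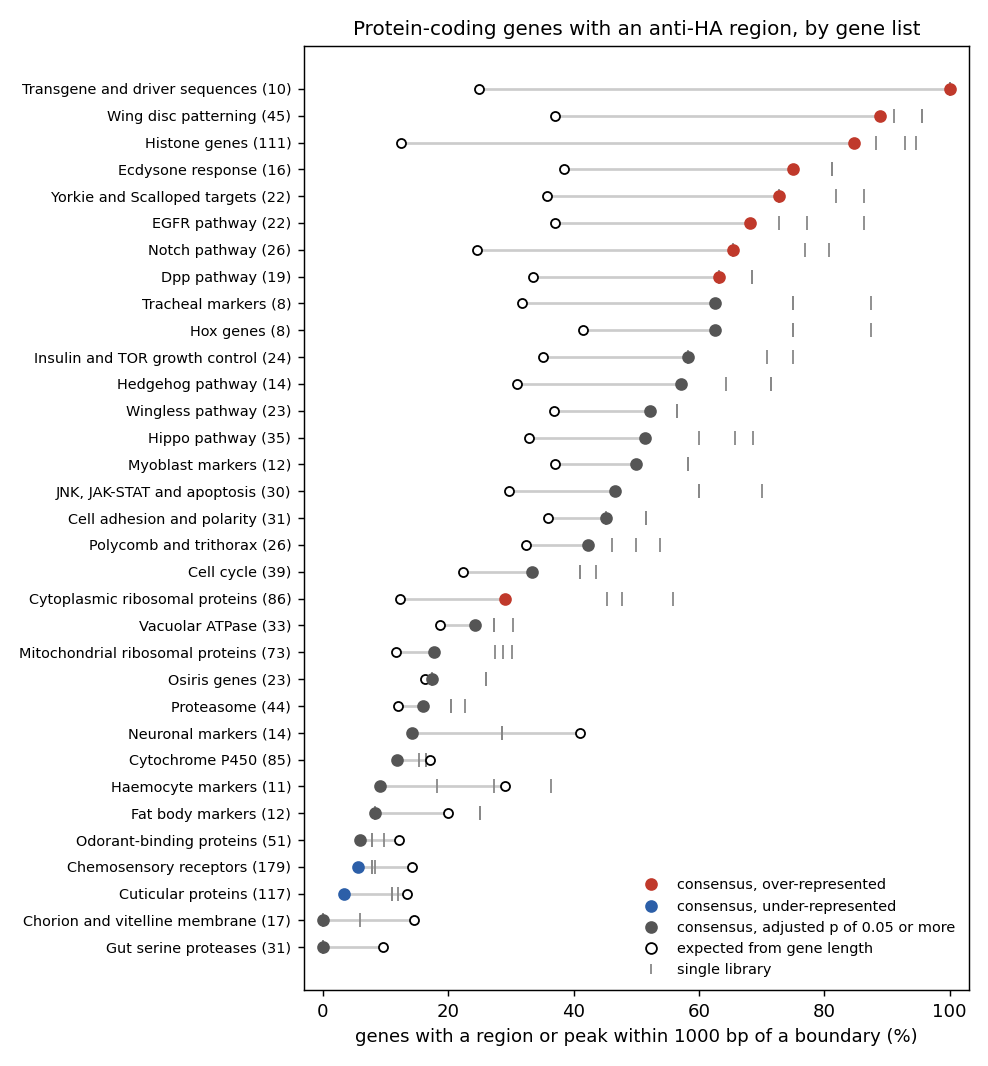
Share of the protein-coding genes of each list, with the list size in parentheses, that had a consensus region or peak within 1000 bp of a gene boundary, in percent. Filled points are consensus regions, open points the share expected from gene length and ticks the 3 single libraries. Wing disc patterning genes stand at 88.9% against 37.1% expected, and chemosensory receptors at 5.59% against 14.3%.

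Among the ribosomal protein, proteasome and vacuolar ATPase lists, the cytoplasmic ribosomal proteins passed the threshold of over-representation. The other lists of this kind had shares above expectation that did not with all 3 libraries and windows of 1000 bp. Chemosensory receptor and cuticular protein genes were bound less often than their length gives. Of 86 cytoplasmic ribosomal protein genes, 25 (29.1%, 12.4% expected, exact stratified test, adjusted p = 0.000218) were bound, led by RpL3 (18.9 ± 1.10; SD, n = 3) and RpS19a (14.3 ± 2.06). This call was lost without length strata (exact adjusted p = 0.0793) and with strata by transcript number (0.508), within a range of 8.80e-12 to 0.508. By the peaks of single libraries, 49.6% ± 5.50 of these genes were bound, against 26.8% ± 1.06 of all protein-coding genes. Mitochondrial ribosomal proteins had 13 of 73 (11.7% expected, exact adjusted p = 0.213), the proteasome 7 of 44 (12% expected, adjusted p = 0.493) and the vacuolar ATPase 8 of 33 (18.7% expected, adjusted p = 0.407). The mitochondrial list passed with regions of at least 2 libraries (20 of 73, exact adjusted p = 0.0232) and with windows of 500 bp (12 of 73, 0.0322), within a range of 0.0232 to 0.708 over 11 alternatives. Chemosensory receptors, which act in sensory neurons, had 10 of 179 (5.59%, 14.3% expected, exact adjusted p = 0.00141). Cuticular proteins, secreted later by the epidermis, had 4 of 117 (3.42%, 13.5% expected, exact adjusted p = 0.00167), of which Ccp84Af and Ccp84Ag shared a region, and with regions of at least 2 libraries 13 of 117 (adjusted p = 0.101, range 8.82e-07 to 0.101). Without replicate 1, 2 or 3 the bound cuticular genes numbered 8, 7 and 6. Odorant-binding proteins had 3 of 51 (exact adjusted p = 0.269), gut serine proteases 0 of 31 (0.130), chorion and vitelline membrane genes 0 of 17 (0.226), cytochrome P450 genes 10 of 85 (0.312) and Osiris genes 4 of 23 (0.778). Gut serine proteases passed as under-represented in 4 of 11 alternatives (exact adjusted p from 0.00282 to 0.567), and the odorant-binding and chorion lists only without length strata (0.0148 and 0.0471).

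Markers of other cells that a dissected disc can hold stood above or below expectation, and none of these lists passed the threshold within length deciles with all 3 libraries and windows of 1000 bp. Tracheal markers had 5 of 8 (31.8% expected, exact stratified test, adjusted p = 0.194), among them vvl (19.8 ± 3.26; SD, n = 3) and trh (19.0 ± 1.36), and without replicate 1 they had 6 of 8 (adjusted p = 0.0484). Markers of myoblasts, which lie beneath the disc epithelium, had 6 of 12 (37.1% expected, exact adjusted p = 0.407), with the boundary region of the muscle factor gene Mef2 at 7.88 ± 0.736. A stronger region inside Mef2 had a mean fold of 18.3, with a percentile of 97.1 against 60.3 for the boundary region. Neuronal markers had 2 of 14 (41.1% expected, exact adjusted p = 0.112), elav (16.7 ± 2.80) and brp (6.01 ± 0.436). The neuronal list passed as under-represented with windows of 500 bp (0 of 14, exact adjusted p = 0.0129) and 2000 bp (2 of 14, 0.0411), within a range of 0.0129 to 0.772 over 11 alternatives. Without length strata the myoblast (0.0332) and tracheal (0.0192) lists passed as over-represented in exact tests. Haemocyte markers had 1 of 11 (exact adjusted p = 0.253), which was crq, and fat body markers 1 of 12 (0.492), which was larp.

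Histone genes and genes whose sequence the transgenes can carry were bound almost throughout, and as lists their regions ranked low by fold. All 10 genes whose sequence the driver, the UAS construct or its marker can carry had a boundary region (24.8% expected, exact stratified test, adjusted p = 4.73e-06). With the higher scoring peaks alone, a cut by fold, 4 of 10 had one (exact adjusted p = 0.146, range 1.30e-07 to 0.146). Of the heat shock gene copies in that list, Hsp70Aa, Hsp70Ab, Hsp70Bb, Hsp70Bbb and Hsp70Bc had folds between 4.26 ± 0.699 and 4.89 ± 1.10 (SD, n = 3), and Hsp70Ba had 18.1 ± 1.68. The driver locus nub had 12.9 ± 1.58, the marker gene w 14.0 ± 2.37 and y 5.27 ± 0.841. bun itself, at 12455540 to 12546611 on 2L, had 15 regions in or near it, from 6.45 ± 1.07 to 18.8 ± 2.11, the strongest at 12507660 to 12508146. Histone genes, clustered repeats on 2L, were bound at 94 of 111 (84.7%, 12.5% expected, exact adjusted p = 1.60e-72). Neighbours share regions there (37 regions for 94 genes), and reads of near-identical copies cannot be assigned with certainty, so both the histone and the Hsp70 values are uncertain.

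Region strength set 5 of 28 lists apart from other bound genes. Besides the Hippo list, wing disc patterning genes ranked high (median percentile 88.6 against 72.1 for random bound genes, permutation test, adjusted p = 0.000560). The transgene list (21.2, permutation adjusted p = 0.000280), histone genes (40.6, adjusted p = 0.000280) and cuticular proteins (30.1, adjusted p = 0.0310) ranked low. The cuticular result rests on 4 bound genes with 3 distinct regions, and the histone result on 94 genes with 37. In the transgene list Hsp70Aa, Hsp70Ab, Hsp70Bb, Hsp70Bbb, Hsp70Bc and y ranked low (percentiles from 8.93 to 24.7). The other members, bun (72.4), nub (88.1), w (90.6) and Hsp70Ba (96.9), did not. The random draws took genes singly, so these adjusted p-values do not allow for shared regions. Nor do they allow for gene length or for the number of boundary regions of a gene, of which the strongest was taken. By −log10 p instead of fold, the transgene list (66.4 against 68.0, permutation adjusted p = 0.943) and histone genes (69.6 against 68.2, adjusted p = 0.869) no longer stood apart, and the Dpp list ranked high (88.9, adjusted p = 0.0403). Without replicate 3, cuticular proteins did not pass (permutation adjusted p = 0.147) and chemosensory receptors did (38.4, adjusted p = 0.0191).

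The X chromosome, which is present in 1 copy in male larvae, had slightly more regions and bound genes than the large autosome arms. Consensus regions stood at 44.9 per Mb on X and 42.4 per Mb on autosomes, a ratio of 1.06, and the ratios of the single libraries' own regions were 1.07, 1.07 and 1.09. Boundary regions lay at 527 of 2197 X-linked genes (24.0%) and at 2312 of 11645 autosomal genes (19.9%), an odds ratio of 1.27 (Fisher's exact test, p = 1.53e-05). X-linked genes were longer, with a median of 2520 bp against 2080 bp, and within length deciles 22.1% were expected to be bound on X (exact stratified test, p = 0.0143). The labels do not give the sex of the larvae.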

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

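The tests on the strongest regions were chosen after their values were seen. Signal outside the chromosomes used above came from 617 regions with a peak in all 3 libraries on 315 other sequences of the assembly, most of them unplaced scaffolds. They had a median fold of 7.39, and 946 ± 55.8 peaks per library (SD, n = 3), 10.3% of all peaks, lay there. Of these regions, 15 lay on the mitochondrial genome, with a median fold of 5.11. With no control library analysed here, these values have no background to compare with.

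The strongest regions of the main chromosomes raise the question of sequence copy number. Of the 58 regions in the top 1% by fold, 7 were on Y, against 32 of all other regions (Fisher's exact test, p = 8.59e-08), although Y had only 39 regions, 10.6 per Mb. Multi-copy sequence of the Y chromosome is a candidate explanation that stays open, since no genome sequence was used here and the copy number under the 7 regions was not measured. Multi-copy sequence outside genes was tested by the share of these regions over 1000 bp from any gene, which was 17.2% against 14.0% for the others (Fisher's exact test, p = 0.450), which decides neither way. The single group gives no biological contrast, and no biological explanation was tested.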

How the results depend on the processing

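Of 86 recomputed values, 68 kept their direction and side of the threshold or stayed close (counts of regions and lists within 1.5 times, other untested values, peaks per library among them, within 1 SD between libraries), 10 moved and 8 became stronger. These totals count lists and hide which ones: 6 of the 11 called lists lost their call in 1 or 2 of 11 alternatives (cuticular proteins, cytoplasmic ribosomal proteins, Dpp, EGFR, ecdysone and transgene), and 3 of 5 strength calls (histone, transgene and cuticular) were lost under 1 setting each. The gene list strata by transcripts or neighbours, regions anywhere in the gene and length strata for X were chosen after the data were seen. On the main chromosomes alone there were 8220 peaks per library, and with the higher scoring peaks of each library 2996 consensus regions; both follow from fewer peaks entering. Leaving out 1 library moved the mean rank correlation between 0.794 and 0.820 and the density ratio of X between 1.06 and 1.08; that ratio was 1.10 with the higher scoring peaks and 1.08 with regions of at least 2 libraries, and the cause was not tested. The number of over-represented lists rose from 9 to 14 with regions of at least 2 libraries and to 18 without strata, with 9 and 8 of the 9 kept. The number of under-represented lists rose from 2 to 4 with windows of 2000 bp and to 5 without strata, with both kept. Without strata the length of developmental genes is no longer allowed for. The bound share of Hippo genes passed the threshold in 8 of 11 alternatives: 54.3% to 57.1% with 1 library left out, 62.9% with regions of at least 2 libraries, 48.6% with windows of 500 bp, 51.4% without strata and with strata by transcripts, and 68.6% with regions anywhere in the gene; it did not with the higher scoring peaks, windows of 2000 bp or neighbour strata, and the cause was not tested. The boundary share of regions, the sharing of peaks, the Yorkie and Scalloped target share and the X-linked gene share kept their calls in every alternative run. No paired analysis was possible because there is a single group. Not run were the motif tests with all their alternatives, which need a genome sequence, and strata by distinct transcription start sites, which the gene table used here does not give. Read depth is unknown, so what it limits in weak regions could not be measured; sharing was 49.9% for lower scoring peaks.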

Other observations

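Tests on myoblast and tracheal markers and on tRNA genes, and the genes of this paragraph other than hth, E2f1, w and rho, were chosen after their values were seen. Some long genes of different kinds held many more consensus regions than genes of similar length (within 30%). hth held 21 regions, against a median of 3 among 88 genes, and sbb, a zinc finger gene, held 19 against a median of 2 among 182. The ecdysone-induced receptor gene Eip75B and the transcription factor gene jing held 18 each, the Hox gene Antp 17 and the BTB gene psq 16, against a median of 1 for psq. The adhesion gene kirre held 17 against a median of 3 among only 5 genes, and Ptp61F, a phosphatase gene, Mur2B and CG1677 held 14 each against medians of 3. Of these counts, those of Mur2B and CG1677 lay below the 95th percentile for their length (15.2 and 14.15), that of Ptp61F equalled it and the others lay above it. The counts include regions of genes nested inside: the strongest region of kirre is the one given above for w, and Ptp61F holds that of rho. E2f1 held 13, against a median of 1 among 420 genes. Of 295 tRNA genes, 120 (40.7%) had a region within 1000 bp, supplied by 65 regions because tRNA genes lie in clusters. Random placements of the consensus regions gave a mean of 9.55% and a maximum of 20.3% (one-sided permutation test, p = 0.005, the smallest that 200 placements can give). tRNA genes are repeated sequences, and reads of identical copies cannot be assigned with certainty.

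The frequent boundary regions of patterning and signalling genes may reflect open chromatin, which the transposase can tag without an antibody. The ribosomal protein, proteasome and vacuolar ATPase lists, grouped as housekeeping genes, had boundary regions at 53 of 236 (22.5%), against 88.9% of wing disc patterning genes (Fisher's exact test, p = 2.03e-17). They were taken by symbol pattern, and whether each gene is active in the disc was not checked. In a pool of these 2 groups, within length deciles, 40 patterning genes were observed and 33.2 expected (exact p = 3.00e-06). That expectation comes from the pool, in which the patterning genes themselves count, and not from all genes of their length. It leaves a smaller gap than 88.9% against 22.5%. A lower housekeeping share was the outcome set beforehand against tagging of open promoters. Equal tagging of every open promoter would not give it if the promoters of all genes in both groups were open in the disc. But every housekeeping list stood above the share expected of its length, cytoplasmic ribosomal proteins with 29.1% against 12.4%. The gap also depends on asking for a peak in every library. By single libraries 49.6% ± 5.50 (SD, n = 3) of cytoplasmic ribosomal genes were bound, against 94.1% ± 2.57 of patterning genes. How open the promoters of each list are was not measured, so tagging that follows openness stays open. Myoblast and tracheal markers had regions in or near 15 of 20 genes (75%), against 97.7% of the other patterning genes, but within length deciles this difference did not pass (exact p = 0.188) and the markers stood above the 47.8% expected of their length (exact p = 0.0138; without the 2 genes that are also on the patterning list 13 of 18, 48.6% expected, exact p = 0.0411), so these attached cells stay open. Myoblast, tracheal, haemocyte and neuronal markers together, also without those 2 genes, stood at 21 of 43 (48.8%, Fisher's exact test, p = 6.03e-08), but no list covered disc epithelium outside the driver domain, where many patterning genes are also active, so that source stays open. Tagging of open enhancers without the antibody stays open too, since 0 control libraries were analysed here, and with a single group no biological explanation was tested.

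The 15 regions at bun raise the question of whether they come from the length of the gene or from the transgene that carries its sequence. Among 144 protein-coding genes within 30% of its length the median was 3 regions and 3 genes held as many as bun. The count of 15 lies above the 95th percentile of 12.6, which argues against gene length as the whole cause. Reads from the transgene copy could add regions on the exons of the expressed isoform; the regions lay in 7 of 10 equal parts of the gene, but exon positions were not used, so this stays open. With a single group, no biological explanation was tested.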
